A study of Mus musculus with 12 samples.

How the data were processed

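RNA was extracted from cultured mouse trophoblast cells with a column kit that yields RNA and DNA together, and stranded mRNA libraries were sequenced on an Illumina instrument, per the labels. The authors trimmed reads with Trim Galore 0.6.7, aligned them to GRCm39 with HISAT2 2.2.1 and estimated gene abundances with Cufflinks 2.2.1. They also named Cuffdiff, without a version, and no table of comparisons was used here. The deposited tables hold 1 library each, with FPKM values per gene (fragments per kilobase of transcript, scaled within each library by its mapped fragments) and the authors' lower and upper confidence bounds in FPKM. The release of the gene annotation and the strand setting were not stated. The 12 tables were read, and the design text speaks of more replicates per group than the 3 analysed here.

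Each table had 57177 rows. Rows of the same gene symbol, or of the same gene identifier where no symbol was given, were summed. This gave 55803 genes, of which 114 had several rows. The 446 rows without a gene identifier, at most 19.3 FPKM, were left out. The genes mt-Co1 and mt-Ts1, with no estimate in 2 pTGC saline libraries because of their depth of coverage, were left out of the tests. The 22 genes with a failed estimate in any library were kept, among them the gene list members Adcy7 and Psg22. Gene types and transcript lengths came from the GENCODE M21 annotation by gene identifier, and its coordinates, which follow GRCm38, were not used. Of the tested genes 14377 had a gene type there, 11644 of them protein-coding.

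Library totals were not given. The fragment number behind each low value was worked out from the width of the authors' confidence interval under Poisson error. Of these numbers 47.7% to 51.5% per library lay within 0.05 of a whole number, where 10% would if they were spread evenly. The FPKM worth of a fragment in the same genes gave the relative depths, from 0.857 to 1.35 with the TSC saline library numbered 1 set to 1. These numbers rest on that assumption and were used to describe depth only. Tests ran on FPKM.

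Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested, which left 14692. Values were log2(FPKM + 1). One limma model (limma 3.58.1, R 4.3.3) with a coefficient for each of the 4 groups was fitted to all 12 libraries, with 8 residual degrees of freedom, and tested with empirical Bayes moderation with an intensity trend, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. The comparisons were oxycodone against saline in pTGC and in TSC, pTGC against TSC under saline and under oxycodone, and the difference of the oxycodone effect between pTGC and TSC. The replicate number of the labels was not stated to mark a shared culture and was a block only in an alternative fit. Correlations of effects are across genes and carry no p.

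The text names genes by a rule that was fixed, like the tests, the gene lists and most alternatives, before the data were examined. For each comparison it takes the 10 most positive and the 10 most negative log2 changes past the threshold whose arms do not overlap, without predicted gene models and pseudogenes, or, where fewer than 10 genes passed, the 5 smallest p values in each direction. It adds up to 4 members with the smallest p per list discussed and 13 marker and opioid receptor genes. The 35 gene lists held 736 genes, of which 539 were tested, and 34 lists had at least 4 tested members. They were tested in limma with camera at a preset correlation between genes of 0.01, with camera with an estimated correlation, and with fry, each adjusted over lists. The 5 comparisons gave 170 list tests. In 14 of these, none past the threshold, the median, the mean and the direction of the camera test differed in sign. Counts of list members are over all tested genes unless they are said to be adjusted over the list alone. Several lists overlap, and a giant cell also expresses many matrix, vascular and fibroblast genes.

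The fit was tested on simulated data, in which each gene had its cell state mean and independent normal errors with its own residual SD. A change was added in 200 genes with a mean of at least 2 FPKM, so the shares recovered do not cover tested genes below that. In the oxycodone comparison in TSC it recovered 16.4% of changes of 0.5 on the log2 scale, 70.1% of changes of 1 and 100% of changes of 2, and in pTGC 26.9%, 76.1% and 95.5%. For the difference of effects it recovered 4.48%, 35.8% and 89.4%. The SD of a gene was the same in all 4 groups, and the pairing of pTGC libraries was not simulated. The shares for pTGC and TSC therefore do not show whether changes are easier to find in either cell state. With a shift of 0.5 added to the FGF and ERK targets, camera at the preset correlation called that list and no other. Since the simulated errors were independent between genes, this cannot show how often that setting makes false calls in the data. There the estimated correlation was 0.392 for this list and 0.836 for mitochondrially encoded genes.

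The alternatives were a pseudocount of 0.1, no filter on low values, an FPKM of at least 5 in 3 libraries, median-of-ratios scaling, quantile normalization, only the 6 libraries compared, the replicate number as a block, library weights, no intensity trend, the row with the highest mean per gene symbol, and leaving out each library in turn. Added after the data were seen were a test against a 2-fold change, the replicate block within the 6 libraries of a cell state, the fit without genes with a failed estimate, the fit without the pTGC libraries numbered 1, and protein-coding genes only. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.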

Results

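Gene expression was measured by RNA sequencing in 12 libraries from mouse trophoblast cells, in 4 groups of 3 libraries each. Trophoblast stem cells (TSC), the self-renewing precursors of the placental trophoblast, were kept undifferentiated with FGF4 and heparin until day 4. Parietal trophoblast giant cells (pTGC), the large invasive hormone-producing cells at the border of the mouse placenta, were obtained from them by retinoic acid treatment until day 6. Each cell state received 10 µg/mL oxycodone, an opioid analgesic, or 0.9% saline at each change of the 2 mL of medium. Cell state therefore went together with the day of collection and with the medium, so the comparisons of pTGC with TSC measure all of these at once. Per library, 12888 to 13544 genes had an FPKM of at least 1. The total number of fragments per library was not given in the tables. The authors' confidence bounds put the depths at 0.857 to 1.35 times that of the TSC saline library numbered 1, and 1 FPKM of the median gene at 42.9 to 62.8 fragments. Expression values below are means ± SD in FPKM with n = 3 libraries per group, log2 changes are differences of mean log2(FPKM + 1), and 14692 genes were tested. Positions are given in GRCm39. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between libraries only.

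The 2 cell states lay far apart. Principal component 1 held 82.3% of the variance and separated the 6 pTGC libraries from the 6 TSC libraries, and principal component 2 held 5.75%. On component 2 the pTGC libraries numbered 1 stood apart from the other pTGC libraries in both arms, at 32.6 under oxycodone and 26.8 under saline, against values of −30.4 to −8.31 in the other 4. Across genes, the correlation between libraries of different arms within TSC had a median of 0.981, as against 0.983 within the oxycodone arm and 0.976 within the saline arm. The same medians in pTGC were 0.970 between the arms, 0.967 within the oxycodone arm and 0.970 within the saline arm.

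**Figure D1:**
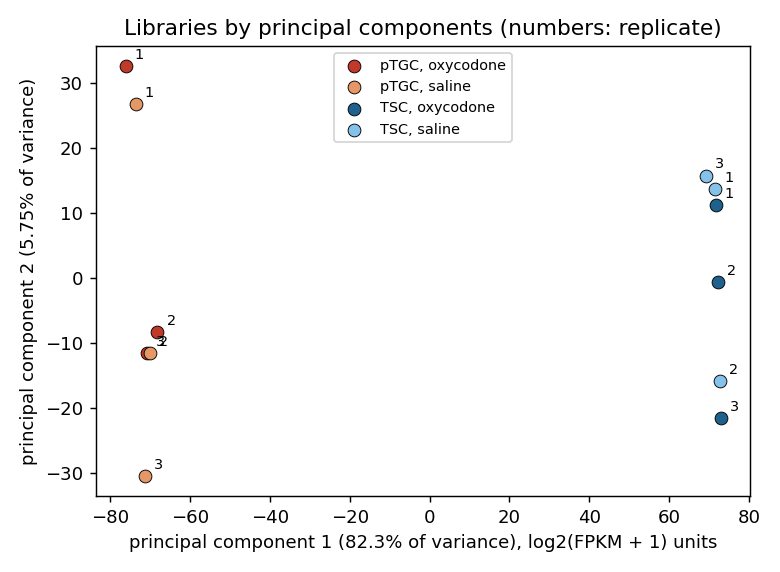
Principal components 1 (82.3% of the variance) and 2 (5.75%) of log2(FPKM + 1) over the tested genes, with 1 point per library, coloured by group and numbered by replicate. Component 1 separates pTGC from TSC, the arms overlap within each cell state, and the pTGC libraries numbered 1 lie at the top, at 32.6 and 26.8 on component 2.

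Under saline, the comparison of pTGC with TSC asked how the giant cells differed from the stem cells they came from. Stem cell transcription factors were lower in pTGC. Cdx2 (ENSMUSG00000029646, chromosome 5, 147237615 to 147244080), which specifies trophectoderm, stood at 0.902 ± 0.553 FPKM in pTGC and 99.9 ± 12.1 in TSC. Eomes (ENSMUSG00000032446) went from 143 ± 25.4 in TSC to 4.27 ± 1.45 in pTGC, Esrrb from 104 ± 25.2 to 2.34 ± 1.38, Elf5 from 264 ± 19.2 to 10.0 ± 2.91 and Sox2 from 187 ± 18.1 to 2.11 ± 0.852. Of the 18 tested members of the list of stem cell markers, 15 were lower and 2 higher in pTGC, with a median log2 change of −3.54. Giant cell genes were higher in pTGC. Prl3d1, placental lactogen I (ENSMUSG00000057170, chromosome 13, 27278173 to 27284241), stood at 179 ± 204 FPKM against 0.0961 ± 0.0725 in TSC, and Prl2c2, a proliferin, at 425 ± 421 against 0.177 ± 0.0986. Hand1, a transcription factor required for giant cells, stood at 506 ± 178 against 193 ± 41.9. Of the 21 tested giant cell markers, 20 were higher, 0 were lower and the median log2 change was 3.66. Apart from prolactin genes, the largest increases were in Tgm2, a transglutaminase induced by retinoic acid (8.05 ± 0.17 SE on the log2 scale), in the serpins Serpinb9e (7.79 ± 0.09 SE), Serpinb9d, Serpinb9b and Serpinb9f, in the iron-siderophore carrier Lcn2 and in the homeobox gene Rhox6. The largest decreases were in Utf1 (−6.02 ± 0.23 SE), Sox2, the heparan sulfate sulfotransferase Hs3st3b1 and Cdx2. Next came the neurofilament gene Nefl, Inpp1, Sox3, the microRNA gene Mir684-2, Ddah1 and Esrrb. In each of these largest changes all 3 pTGC libraries lay on the same side of all 3 TSC libraries, which the naming rule requires. Mir684-2 varied widely, at 0, 39.2 and 0 FPKM in pTGC against 74.2, 140 and 161 in TSC. Under oxycodone its cell states overlapped, with 165 in a pTGC library and 130 in a TSC library.

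**Figure D2:**
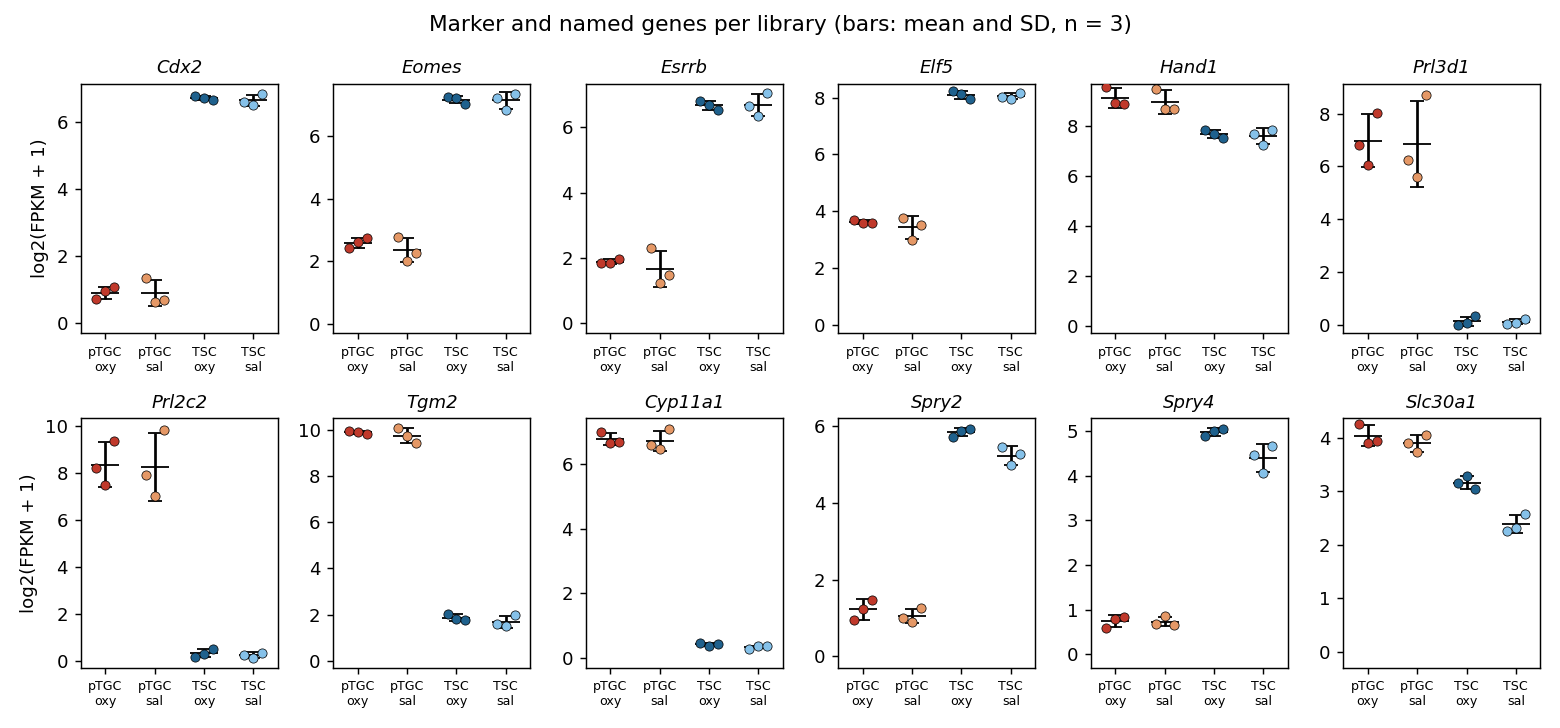
Expression of 12 genes as log2(FPKM + 1) per library, with 1 point per library and bars for the mean and SD of the 3 libraries of each group. The stem cell genes Cdx2, Eomes, Esrrb and Elf5 are high in TSC, Prl3d1, Prl2c2, Tgm2 and Cyp11a1 are high in pTGC, and Spry2, Spry4 and Slc30a1 have higher means in oxycodone-treated than in saline-treated TSC without passing the test over all genes.

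In this comparison limma found 10201 of the 14692 genes past an adjusted p of 0.05, with 4637 higher and 5564 lower in pTGC (5137 and 4929 after median-of-ratios scaling), and the smallest adjusted p was 2.30e-13. At least 2-fold differences on the log2(FPKM + 1) scale were estimated for 2227 of the higher and 2179 of the lower genes. Tested against a 2-fold difference itself, a choice made after the data were seen, 1301 genes were higher and 1064 lower. Scaling the libraries by median-of-ratios moved the median gene by 0.110 under saline and by 0.123 under oxycodone on the log2 scale, and the direction of no list reported in this comparison turned. The prolactin family (Prl2c, Prl3d) and the Serpinb9 genes hold near-identical members, so the share of each member in their common reads is uncertain.

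Retinoic acid targets and steroid hormone genes were higher in pTGC, and genes of the FGF pathway were lower. Of 16 tested retinoic acid targets 13 were higher and 2 lower (median log2 change 2.12), including Cyp26b1, which degrades retinoic acid (58.5 ± 15.0 against 0.133 ± 0.0248 FPKM), Dhrs3 (113 ± 18.6 against 1.70 ± 0.147) and Hic1. Of 10 steroidogenic genes 8 were higher and 1 lower (median 2.15), including Cyp11a1, the side-chain cleavage enzyme (106 ± 24.7 against 0.266 ± 0.0333), Star and Hsd3b6. Of 17 FGF and ERK targets 11 were lower and 4 higher (median −1.21). Etv4 stood at 0.619 ± 0.295 FPKM in pTGC against 49.5 ± 5.05 in TSC, Etv5 at 0.391 ± 0.135 against 27.5 ± 5.59, and the feedback inhibitor Spry2 at 1.07 ± 0.268 against 36.9 ± 6.18. The medium of TSC contained FGF4 and that of pTGC retinoic acid. With camera at its preset correlation, the adjusted p was 8.76e-05 for retinoic acid targets, 0.00155 for steroidogenesis and 0.0196 for FGF and ERK targets. With an estimated correlation the camera adjusted p values were 0.220, 0.220 and 0.488. Fry passed 32 of the 34 lists in this comparison (smallest adjusted p 1.17e-08). It tests a list on its own and not against the other genes, of which most passed here (10201 of 14692).

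Cell division genes were lower in pTGC, which replicate their DNA without dividing. All 29 tested mitosis genes were lower (median log2 change −1.83), among them the kinase Aurka (17.0 ± 0.721 against 67.1 ± 0.721 FPKM), the checkpoint kinase Bub1 (7.50 ± 1.41 against 36.7 ± 2.68), the cyclin Ccnb1 and Cenpf. Of 31 genes of S phase 25 were lower and 2 higher (median −0.97), including Rrm2, Gins1, Mcm5 and Pole. Of 22 p53 targets and cell cycle inhibitors 15 were higher and 3 lower, including the inhibitors Cdkn1a (112 ± 18.5 against 15.0 ± 2.39) and Cdkn1c (656 ± 145 against 136 ± 13.5). Of 31 ribosomal protein genes 28 were lower and 0 higher (median −0.78), among them Rpl3 and Rpl8. The adjusted p from camera with an estimated correlation was 0.305 for mitosis, 0.321 for S phase, 0.424 for the p53 list and 0.488 for ribosomal proteins. At the preset correlation it was 2.12e-10, 0.000202, 0.00424 and 0.000427.

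Matrix and vascular genes were mostly higher in pTGC, and lists of stress genes differed among themselves. Of 23 genes of the extracellular matrix and basement membrane 20 were higher and 1 lower, including the collagen chaperone Serpinh1 (81.5 ± 6.71 against 6.62 ± 1.01 FPKM), Loxl2, Fn1 and Ccn2. Of 18 angiogenic and vascular factors 12 were higher and 3 lower, including the vasodilator peptide gene Adm (54.6 ± 17.7 against 0.218 ± 0.0142) and the anticoagulant receptor Thbd (67.5 ± 21.7 against 0.487 ± 0.0449). The unfolded protein response had 13 of 22 members higher and 4 lower, with Ddit3 at 53.6 ± 3.15 against 3.11 ± 0.617. Higher and lower members numbered 12 and 2 of 15 interferon and antiviral genes, 9 and 0 of 11 NF-kB and cytokine genes, 10 and 3 of 15 immediate early genes and 6 and 3 of 12 heat shock genes. Cholesterol biosynthesis went the other way, with 17 of 23 members lower and 2 higher, including Mvd (3.44 ± 0.419 against 29.3 ± 2.27) and Idi1. With an estimated correlation the camera adjusted p was 0.321 for matrix, 0.321 for vascular factors, 0.323 for the unfolded protein response, 0.220 for interferon genes, 0.323 for NF-kB genes, 0.424 for immediate early genes and 0.347 for cholesterol biosynthesis. These 7 lists had passed at the preset correlation, and heat shock genes had not (camera adjusted p = 0.153).

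Metabolic and transport genes moved in both directions. Of 27 genes of glycolysis and the hypoxia response 16 were lower and 8 higher in pTGC, with Pdk1 at 2.87 ± 0.364 FPKM against 69.3 ± 4.92 in TSC and the glucose transporter Slc2a3 at 0.724 ± 0.281 against 13.1 ± 2.22, while Adm and Vegfa were higher. Of 26 nuclear genes of oxidative phosphorylation 12 were lower and 1 higher, of 18 nutrient transporters 8 were lower and 5 higher, and of 21 NRF2 targets 9 were lower and 6 higher. Of 23 imprinted genes of the placenta 10 were higher, such as Sgce and Slc38a4, and 9 lower, such as Mest. None of these 5 lists passed with camera, with adjusted p values of 0.153, 0.0798, 0.479, 0.622 and 0.356 at the preset correlation. Of the 12 tested mitochondrially encoded genes 7 were higher and 0 lower (camera adjusted p = 0.0394 at the preset correlation, adjusted p = 0.593 with an estimated correlation). Of 6 replication-dependent and linker histone genes 5 were higher and 0 lower (0.0176 at the preset correlation, adjusted p = 0.347 with an estimated correlation in camera). Most replication-dependent histone transcripts lack a poly(A) tail.

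Markers of other cells were present at several levels. Of 7 spongiotrophoblast and glycogen cell markers 4 were higher and 1 lower in pTGC, and of 13 labyrinth and syncytiotrophoblast markers 7 were higher, including Syna, and 3 lower, including Epcam (13.8 ± 1.86 against 140 ± 9.35 FPKM). Of 9 fibroblast markers 8 were higher and 1 lower (median log2 change 2.33), including the actin-associated genes Tagln (65.1 ± 7.28 against 0.265 ± 0.0896) and Acta2 (24.6 ± 4.46 against 0.134 ± 0.0248). Of 9 extraembryonic endoderm markers 5 were higher and 1 lower, including Pdgfra (15.4 ± 2.79 against 1.01 ± 0.0848). Of 6 endothelial and blood cell markers 4 were higher and 1 lower, including Csf1r (48.7 ± 15.4 against 0.237 ± 0.0529) and Cdh5 (45.8 ± 18.1 against 0.162 ± 0.0455). Of 9 embryonic stem and epiblast markers 5 were lower and 1 higher, and of 6 neural markers 4 were lower and 1 higher. At the preset correlation camera called the fibroblast and endoderm lists (adjusted p 0.000625 and 0.0423) and with an estimated correlation neither (adjusted p = 0.323 and adjusted p = 0.424). The spongiotrophoblast, labyrinth, endothelial, epiblast and neural lists did not pass at the preset correlation (camera adjusted p 0.296, 0.145, 0.119, 0.0765 and 0.0799).

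Under oxycodone, the same comparison of pTGC with TSC asked whether the giant cell programme was present in treated cultures. Limma found 10307 genes past the threshold, with 4635 higher and 5672 lower in pTGC, and after median-of-ratios scaling 5192 higher and 4979 lower. The largest increases were in Prl2c3, Prl2c2, Tgm2 (943 ± 42.7 against 2.66 ± 0.382 FPKM), Lcn2, Prl7a1, Serpinb9e, Serpinb9d, Rhox6, Rhox9 and Serpinb9b. The largest decreases were in the small nucleolar RNA gene Snord32a, which was listed at 0 in the 3 pTGC libraries, and in Nefl, Cdx2 (0.888 ± 0.229 against 105 ± 5.11), Hs3st3b1, Utf1, Sox3, Inpp1, Sox2, Etv4 and Bmp4. Snord32a varied widely within groups under saline, at 0, 0 and 110 FPKM in pTGC and 0, 0 and 152 in TSC. This comparison shares no library with that under saline. The 2 comparisons had 4249 higher genes in common, where 1463 would be shared if the calls were independent, 5039 lower genes in common (2148 if independent) and 2 genes called in opposite directions. Across genes the log2 changes of the 2 comparisons had a Pearson correlation of 0.967 and a Spearman correlation of 0.955, and genes are not independent replicates. As under saline, 20 of 21 giant cell markers were higher, 15 of 18 stem cell markers lower and 29 of 29 mitosis genes lower, with camera adjusted p values of 5.92e-09, 2.25e-05 and 5.78e-09 at the preset correlation. The estimated correlation gave adjusted p = 0.208, adjusted p = 0.309 and adjusted p = 0.299. Fry, which tests each list on its own, passed 31 of 34 lists (smallest adjusted p 1.22e-08). Of 12 mitochondrially encoded genes 0 passed (median log2 change 0.12, camera adjusted p = 0.445 at the preset correlation), and none of the 12 differed past the threshold between the 2 comparisons. Camera called the difference of this list between the comparisons at the preset correlation (adjusted p = 2.75e-05) and not with an estimated correlation (camera adjusted p = 0.843).

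In TSC, oxycodone was compared with saline to find the transcriptional response of stem cells to the drug. The stem cell genes had similar means in both arms, with Cdx2 at 105 ± 5.11 FPKM under oxycodone and 99.9 ± 12.1 under saline, Eomes at 145 ± 11.3 and 143 ± 25.4, Esrrb at 102 ± 9.95 and 104 ± 25.2 and Elf5 at 274 ± 24.8 and 264 ± 19.2. The smallest p values belonged, among genes with a higher mean under oxycodone, to the homeobox gene Dlx1 (2.13 ± 0.123 against 1.06 ± 0.0892), Oxct2b (9.88 ± 0.871 against 5.92 ± 0.395), the zinc exporter Slc30a1 (ENSMUSG00000037434, chromosome 1, 191638879 to 191645359; 7.93 ± 0.766 against 4.25 ± 0.620), the small nucleolar RNA gene Snora73b and Usp36. Among genes with a lower mean they belonged to Prr15l (0.719 ± 0.104 against 1.81 ± 0.385), the adhesion molecule Nectin2 (17.7 ± 2.18 against 26.9 ± 2.11), Wdr76, Xlr5c and the receptor Erbb3 (14.3 ± 1.39 against 21.3 ± 2.33). None of these passed the limma test over all genes, and the smallest adjusted p was 0.372. Limma found 0 genes past the threshold, and 520 genes had an unadjusted p under 0.05, with 234 higher and 286 lower. With independent libraries and no effect on any gene 735 would be expected. Some TSC libraries of different arms and numbers deviated alike from their group means, with correlations across genes of up to 0.436, so 520 cannot be read against it. The 95% confidence interval of the log2 change had a median half-width of 0.322, and it excluded a change of 1 on the log2(FPKM + 1) scale in 95.4% of the genes. Near 1 FPKM a change of 1 on this scale is more than 2-fold in FPKM. With library weights in the fit the count rose to 395, in a fit that gave 1 oxycodone library a weight of 139 and the others weights of 0.268 to 2.27. It was 3 without the TSC oxycodone library numbered 3 and 1 without the TSC saline library numbered 2.

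By gene list, FGF and ERK targets had the largest median in oxycodone-treated TSC. The 17 tested members had a median log2 change of 0.35, and 12 were positive. Spry4 (chromosome 18, 38719300 to 38734468) stood at 30.4 ± 1.78 FPKM under oxycodone against 20.3 ± 4.42, and Spry2 (chromosome 14, 106129381 to 106134253) at 56.3 ± 4.23 against 36.9 ± 6.18, with the 3 oxycodone libraries above the 3 saline libraries for both. Ier3 stood at 14.3 ± 0.972 against 10.6 ± 2.48 and Dusp5 at 14.4 ± 0.630 against 10.6 ± 2.19. Adjusted over the list alone 2 of the 17 passed (Spry2 and Spry4, limma adjusted p = 0.0242 each), and 0 passed over all genes. Camera gave the list an adjusted p of 1.54e-05 at the preset correlation, and adjusted p = 0.758 with an estimated correlation. The median was 0.19 without the saline library numbered 2. Mitosis genes had a median of −0.15, with 2 of 29 positive and Cenpf at 10.8 ± 1.44 against 14.6 ± 2.21. Cholesterol biosynthesis genes had a median of −0.13, with 5 of 23 positive and Hmgcs1 at 27.6 ± 5.80 against 36.4 ± 4.31. The 12 mitochondrially encoded genes had a median of 0.28 and all were positive, and their share of all FPKM ranged from 5.55% to 10.8% in the oxycodone libraries and from 4.82% to 8.36% in the saline libraries. The camera adjusted p values of the last 3 lists were 2.07e-06, 0.000840 and 0.00700 at the preset correlation, and with an estimated correlation adjusted p = 0.758, adjusted p = 0.758 and adjusted p = 0.946. Adjusted over the list alone, Slc30a1 passed among the nutrient transporters (limma adjusted p = 0.00217) and Cebpa among the labyrinth markers (0.0341; 6.88 ± 0.528 against 4.57 ± 0.724 FPKM), with the 3 oxycodone libraries above the 3 saline libraries for both genes.

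**Figure D3:**
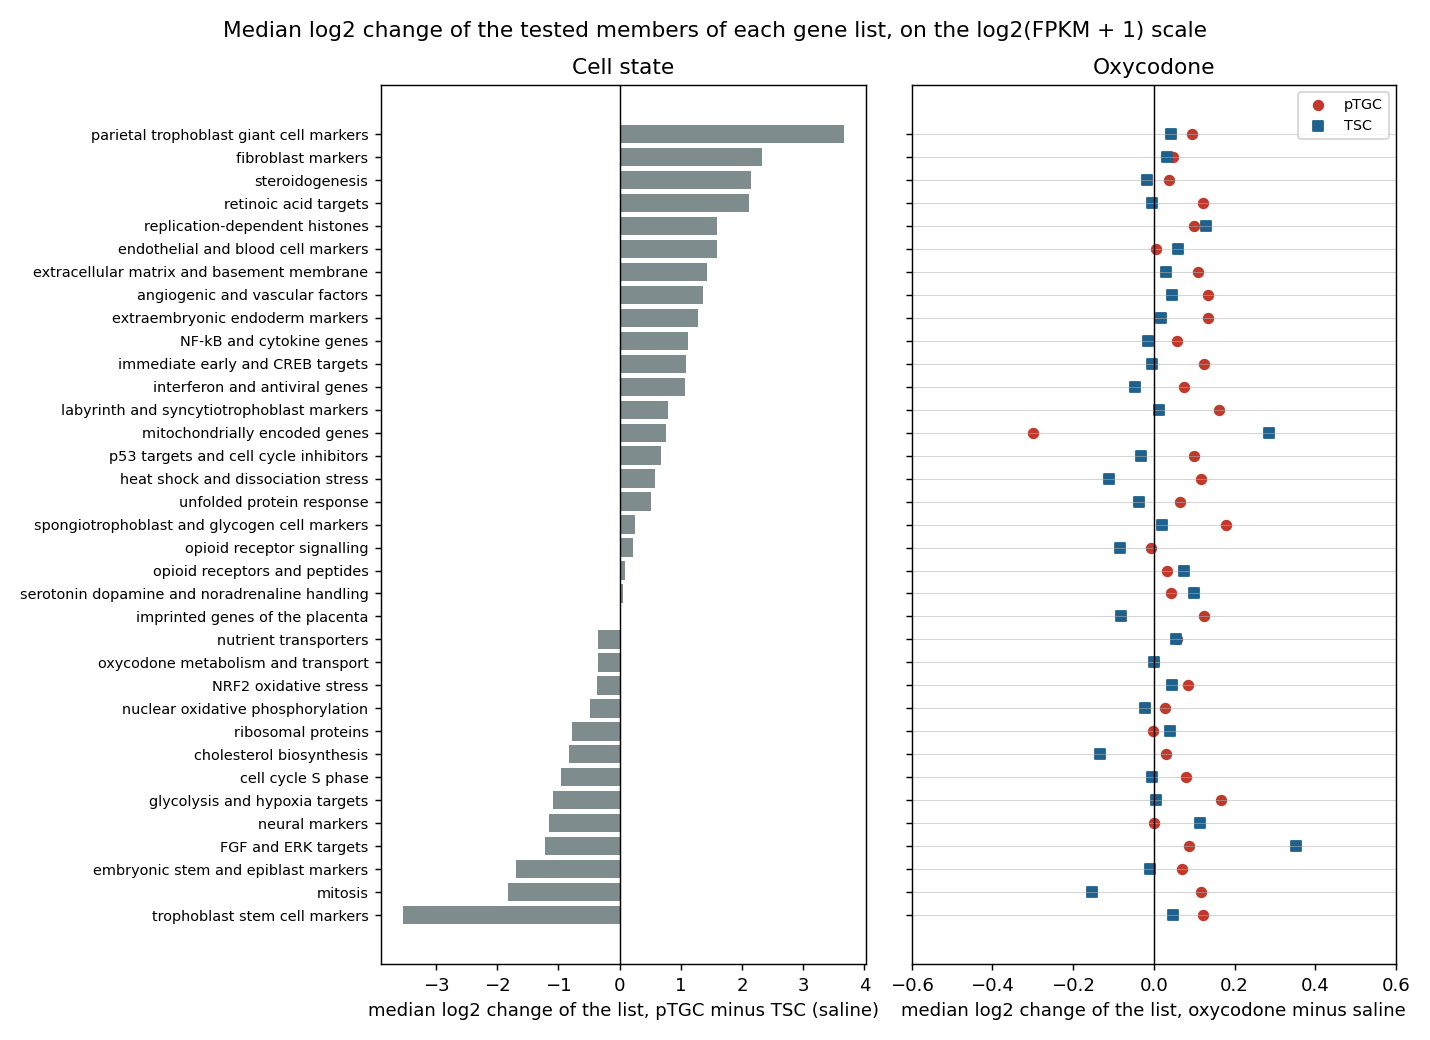
Median log2 change of the tested members of each of 35 gene lists, on the left for pTGC minus TSC under saline (bars) and on the right for oxycodone minus saline in pTGC (circles) and TSC (squares). On the left the medians run from −3.54 for stem cell markers to 3.66 for giant cell markers, and on the right, where the axis is narrower, from −0.30 for mitochondrially encoded genes in pTGC to 0.35 for FGF and ERK targets in TSC.

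In pTGC, oxycodone was compared with saline to find the response of the giant cells. Among giant cell genes, Hand1 stood at 563 ± 166 FPKM under oxycodone and 506 ± 178 under saline, Prl3d1 at 146 ± 102 and 179 ± 204, and Prl2c2 at 375 ± 246 and 425 ± 421. Hand1 was higher under oxycodone within each replicate number (754 against 711, 474 against 403 and 459 against 403). Its mean was lower under oxycodone (467 against 506) without the oxycodone library numbered 1. That comparison kept the saline library numbered 1, the highest of its arm. For both prolactin genes the direction depended on the scale and on single libraries. On the log2(FPKM + 1) scale of the test both had a higher mean under oxycodone with all libraries kept. Within replicate numbers 1, 2 and 3 Prl3d1 stood at 113 against 74.5, 65.1 against 47.8 and 260 against 413 FPKM. Prl2c2 was likewise higher under oxycodone in numbers 1 and 2 and lower in number 3. The direction of the FPKM means turned without the oxycodone library numbered 2 (186 against 179 for Prl3d1, 473 against 425 for Prl2c2). Without the saline library numbered 3 the saline means were 61.2 for Prl3d1 and 184 for Prl2c2, so that the direction turned, without the oxycodone library numbered 3 the oxycodone means were 88.9 and 236, and without both the oxycodone means were the higher. Among residual stem cell transcripts, Cdx2 stood at 0.888 ± 0.229 and 0.902 ± 0.553 and Eomes at 5.06 ± 0.673 and 4.27 ± 1.45. Among genes with a higher mean under oxycodone, the smallest p values belonged to the zinc finger gene Zfp444 (ENSMUSG00000044876, chromosome 7, 6175225 to 6196810; 7.04 ± 0.342 against 5.03 ± 0.0623), Ptprcap, Ccdc184, Tmem265 and Rinl. Among genes with a lower mean they belonged to the ciliary transport gene Ift172 (1.61 ± 0.332 against 2.80 ± 0.237), the synaptotagmin Syt12 (0.698 ± 0.105 against 1.18 ± 0.0592), the chromatin remodeller Chd3, Pcf11 and Pnisr (21.3 ± 0.960 against 33.4 ± 4.65). None of these genes passed. Limma found 0 genes past the threshold (smallest adjusted p 0.441), and 302 genes had an unadjusted p under 0.05, with 86 higher and 216 lower. With independent libraries and no effect on any gene 735 would be expected, but the pTGC arms were paired by number, so 302 cannot be read against it. The 95% confidence interval excluded a change of 1 on the log2(FPKM + 1) scale in 95.8% of the genes. This interval takes 1 spread per gene over all 4 groups, so it is too narrow for genes that vary more in pTGC than in TSC. The replicate numbers paired the libraries of the 2 arms in pTGC, and with the number as a block limma again found 0 genes, both in all 12 libraries and in the 6 pTGC libraries alone. The fit to 6 libraries leaves few residual degrees of freedom. The fit to 12 libraries takes the same effect of the number in pTGC and TSC. Neither is therefore a strong test of changes within the pTGC pairs. The count was 1 without the saline library numbered 3 and 1 without both libraries numbered 1.

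No member of a gene list passed in oxycodone-treated pTGC, over all genes or adjusted over the list alone. Camera at the preset correlation called 11 of 34 lists, 10 of them with a positive direction, and 0 with an estimated correlation (smallest adjusted p = 0.696). The mitochondrially encoded genes were the 1 list with a negative direction. Their median log2 change was −0.30 and 1 of 12 was positive, with mt-Nd4 at 1543 ± 240 FPKM against 1978 ± 137 (camera adjusted p = 0.00271 at the preset correlation, adjusted p = 0.696 with an estimated correlation). The call was also lost after quantile normalization. The largest positive medians were those of spongiotrophoblast and glycogen cell markers (0.18, 6 of 7 positive), glycolysis and hypoxia targets (0.17, 22 of 27) and labyrinth markers (0.16, 12 of 13; Ly6e at 55.3 ± 12.7 against 40.9 ± 5.88 FPKM). Mitosis genes had a median of 0.12 with 27 of 29 positive (Ccna2 at 20.9 ± 1.18 against 18.4 ± 1.81). The preset camera adjusted p values of these 4 lists were 0.0470, 0.00432, 0.00271 and 0.00271, and with an estimated correlation each had an adjusted p = 0.696. The call for the spongiotrophoblast list was also lost under both other scalings. Stem cell markers (median 0.12, 15 of 18 positive) and the heat shock and dissociation stress genes, a list on sample quality (median 0.12, 11 of 12 positive), were among the lists called as well, each with a camera adjusted p of 0.0267 at the preset correlation and adjusted p = 0.696 with an estimated correlation. The call for heat shock genes was lost after quantile normalization. Fry, which asks whether a list moves on balance in one direction, gave 0 lists past the threshold in pTGC (smallest adjusted p 0.775) and 0 in TSC (0.936). The mixed test of fry, which asks for change in either direction, passed 1 list in TSC, the nutrient transporters (fry adjusted p = 0.0479), and 0 in pTGC (smallest adjusted p 1.00).

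The prolactin family varied between pTGC libraries of the same arm. The 11 tested genes summed to 1482, 795 and 3055 FPKM in the oxycodone libraries numbered 1, 2 and 3, and to 1109, 698 and 4858 FPKM in the saline libraries with the same numbers. The libraries numbered 3 held 3.84 times the sum of those numbered 2 under oxycodone and 6.96 times under saline. The spread behind the oxycodone comparison of Prl3d1 and Prl2c2 was therefore wide, with standard errors of 0.66 and 0.60 on the log2 scale against a median of 0.15 over all genes. These standard errors take 1 spread per gene over all 4 groups. In TSC both genes lay below 1 FPKM in every library, so for them the spread in pTGC is understated.

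**Figure D4:**
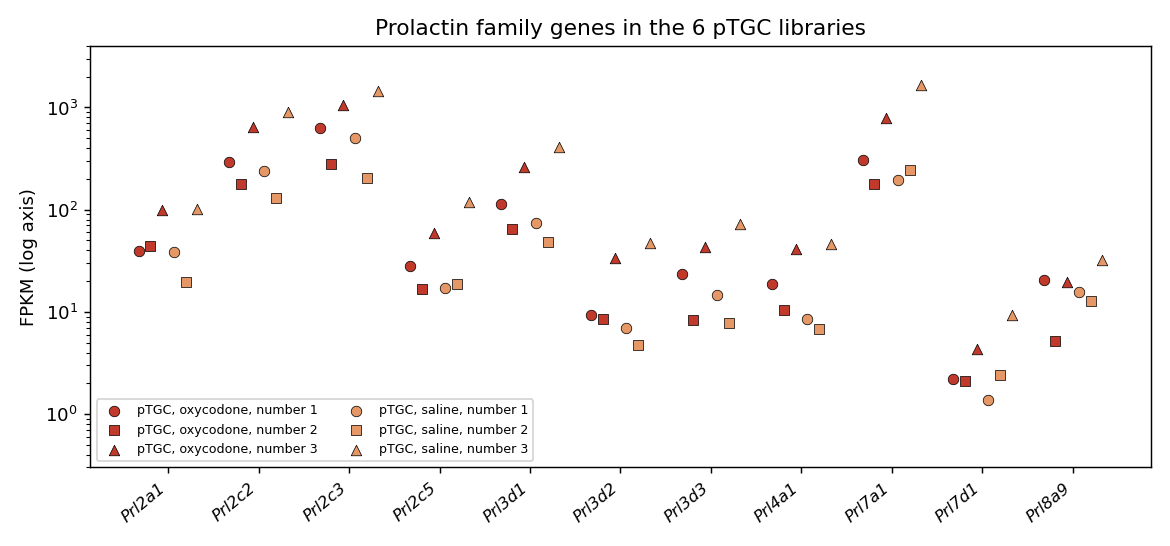
FPKM of the 11 tested prolactin family genes in the 6 pTGC libraries on a log axis, with colour for the arm and marker shape for the replicate number. In the saline arm the library numbered 3 is the highest for all 11 genes, and the family sums span 698 to 4858 FPKM under saline and 795 to 3055 FPKM under oxycodone.

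The difference between the oxycodone effects in pTGC and TSC was tested gene by gene to ask whether the 2 cell states responded differently. The smallest p values belonged to Nectin2 (50.6 ± 0.733 FPKM under oxycodone against 45.8 ± 2.16 in pTGC, and 17.7 ± 2.18 against 26.9 ± 2.11 in TSC), Zfp444, Rnf169, Prr15l and the kinetochore motor gene Cenpe on the positive side. On the negative side they belonged to Oxct2b, Sgsm3 (2.70 ± 0.292 against 3.42 ± 0.333 in pTGC, and 4.80 ± 0.386 against 3.74 ± 0.196 in TSC), the synaptobrevin gene Vamp2, Pcf11 and Snora73b. None passed. Limma found 0 genes past the threshold (smallest adjusted p 1.00), with 413 genes at an unadjusted p under 0.05, 180 of them positive and 233 negative. The median half-width of the 95% confidence interval was 0.455 on the log2 scale, and the interval excluded a difference of 1 on that log2(FPKM + 1) scale in 87.6% of the genes. The count was 1 without the pTGC saline library numbered 3 and 1 without both pTGC libraries numbered 1. Across the 14692 genes, which are not independent replicates, the 2 oxycodone effects had a Pearson correlation of −0.0836 and a Spearman correlation of −0.0636, and 46.8% of the genes had the same sign in both. Leaving out 1 library at a time gave Pearson values of −0.234 (without the TSC oxycodone library numbered 1) to 0.164 (without the TSC oxycodone library numbered 3).

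The opioid receptor genes had very low values in all 4 groups. The µ-opioid receptor gene Oprm1 (ENSMUSG00000000766, chromosome 10, 6708506 to 6988198) was above 0 in 1 of the 12 libraries, at 0.0263 FPKM. The highest value in any library was 0.166 FPKM for the δ receptor gene Oprd1, 0.0440 for the κ receptor gene Oprk1 and 0.181 for the nociceptin receptor gene Oprl1, and none of the 4 met the expression filter. Of the list of opioid receptors and peptides 3 genes were tested, of which Ogfr was higher (33.3 ± 3.36 against 24.1 ± 2.04 FPKM) and Ogfrl1 lower in pTGC than in TSC under saline, and Pomc did not pass. Of 20 tested genes of opioid receptor signalling 9 were higher and 4 lower in pTGC, including the adenylyl cyclase Adcy3 among the higher and the arrestin Arrb2 (5.55 ± 0.543 against 27.3 ± 1.40 FPKM) among the lower. Of 6 genes of oxycodone metabolism and transport 2 were higher, Por and Cyp2d22, and 2 lower, Abcc1 and Abcb1b. Of 4 genes of serotonin, dopamine and noradrenaline handling 2 were higher, Htr1d and Comt, and 2 lower, Maoa and Ddc. Camera called none of the last 3 lists between the cell states (adjusted p 0.316, 0.883 and 0.622 at the preset correlation), and no member of the 4 lists passed limma between oxycodone and saline in either cell state. The spongiotrophoblast marker Tpbpa was also too low to test. Its highest values, 3.31 and 2.41 FPKM, were in the pTGC oxycodone and saline libraries numbered 3, and the other pTGC libraries held at most 0.190. Ascl2, its regulator, did not differ past the threshold between pTGC and TSC under saline (1.23 ± 0.654 against 1.18 ± 0.296 FPKM).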

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

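The tests of a trend on transcript length, of single libraries, of other divisions and of permuted arms were fixed before their results were seen, except the rule that a leave-one-out share is undecided where its bootstrap interval over list members spans the bound of 0.5 and the permutation of the pTGC arms within pairs, which were added after.

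For 6 gene lists camera, at the preset correlation, found that the oxycodone effect differed between pTGC and TSC. The median difference of effects, pTGC minus TSC on the log2 scale, was −0.21 for FGF and ERK targets, 0.26 for mitosis, 0.14 for cholesterol biosynthesis, 0.16 for imprinted genes of the placenta, −0.61 for mitochondrially encoded genes and 0.22 for heat shock genes. The camera adjusted p values were 0.0209, 1.45e-08, 0.00401, 0.00561, 2.75e-05 and 0.0209. With an estimated correlation adjusted p = 0.843 for all 6, and no single gene differed past the threshold. The call for FGF and ERK targets was lost without the pTGC libraries numbered 1, and that for heat shock genes after quantile normalization.

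The targets of FGF and ERK signalling, which includes feedback inhibitors such as Spry2 and Spry4, had a median log2 change of 0.35 in oxycodone-treated TSC, whose medium holds FGF4. A trend on transcript length between libraries was argued against, since subtracting it left 1.01 of the median. A single library stays open: without the TSC saline library numbered 2 the median was 0.19, or 0.543 of its value, and the bootstrap interval of that share was too wide to decide. The real division of the 6 TSC libraries was the 1 of 10 with a median as large, the highest other being 0.23, and with 10 divisions a share below 0.05 cannot be reached. An effect of oxycodone on the response to FGF4 stays open and was not tested.

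The mitochondrially encoded genes had a lower mean under oxycodone in pTGC and a higher mean in TSC, with a difference of effects of −0.585 as a mean over 12 genes. Their level moves as a block between libraries of the same group, from 4.82% to 8.36% of all FPKM in TSC saline and from 5.55% to 10.8% in TSC oxycodone. In pTGC the arms did not overlap in this share, at 6.95% to 10.2% under oxycodone and 10.7% to 11.7% under saline. They did overlap in the mean log2 over the 12 genes, on which the difference of effects and the permutations rest. There the oxycodone library numbered 3 stood at 11.37, above the saline library numbered 1 at 11.32. Permuting the arms within each cell state gave a two-sided exact permutation p of 0.205 over 400 arrangements. In pTGC, where the numbers pair the libraries, oxycodone minus saline was −0.23, −0.50 and −0.16 for numbers 1, 2 and 3. Exchanging the pTGC arms only within these pairs gave an exact permutation p of 0.20 over 160 arrangements. The spread between single libraries therefore stays an open explanation. The pTGC effect alone cannot have a p under 0.25 with 3 pairs. Without the TSC oxycodone library numbered 3 the difference was −0.292, or 0.499 of its value, which is at the bound and leaves the part of that library open. Without the TSC saline library numbered 3 it was −0.336, so the value depends on 2 TSC libraries. A difference in the response of the 2 cell states stays open as well, untested beyond this.

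Other divisions of the libraries were run for each count of genes. For oxycodone against saline the real count was 0 in pTGC and 0 in TSC, so all 10 of 10 divisions gave as many by construction, with a highest other count of 2 and of 4. In pTGC, where the numbers pair the libraries, the real division parts all 3 pairs, and the other 3 divisions that do so gave 0, 1 and 1 genes. For pTGC against TSC, 1 of 10 divisions, the real one, gave as many genes, with 10201 under saline against a highest other of 3, and 10307 under oxycodone against a highest other of 1. Shares below 0.05 cannot be reached with 10 divisions in these 4 comparisons. For the difference of effects, where the count was 0, 100 of 100 drawn divisions gave as many by construction, with a highest other of 5, and the test says nothing about chance there.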

How the results depend on the processing

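Of the alternatives, those named in the methods as added were chosen after the data were seen. Without the filter on low values limma called 3 genes in oxycodone against saline in pTGC, 5 in TSC and 2 in the difference of effects, all below 1 FPKM and so outside the filtered test. Library weights gave 395 genes in TSC, 201 of them higher, in a weighting that stopped before it converged and leaned on 1 oxycodone library. Without the pTGC libraries numbered 1 the counts were 1 in pTGC and 1 in the difference of effects (Gm11702). Leaving out 1 library gave counts of 0 to 1 in pTGC (1 without the saline library numbered 3, Gm25776), 0 to 3 in TSC (3 without the oxycodone library numbered 3, Gm12238, Gm2007 and Snord89, and 1 without the saline library numbered 2, ENSMUSG00002074947), and 0 to 1 in the difference of effects (1 without the pTGC saline library numbered 3). These genes fall outside the naming rule and were chosen after their values were seen. Several were listed at 0 in all remaining libraries of an arm. The cause of the other changes was not tested. The counts for pTGC against TSC kept within 1.5 times of 10201 and 10307, at 7408 to 12818 and 7449 to 12807, lowest with the FPKM minimum of 5 and highest without a filter, which change the number of genes tested. Under saline 45.5% and under oxycodone 45.0% of the called genes were higher in pTGC, and after median-of-ratios scaling 51.0% in both. The correlation of the oxycodone effects was −0.137 to −0.0474 under other settings and −0.234 to 0.164 with 1 library left out (0.0546 without the pTGC oxycodone library numbered 1, 0.0558 without the TSC saline library numbered 3), so its sign is not fixed by these data. With the replicate block, protein-coding genes only, and the other alternatives, the counts for oxycodone were 0. The estimated correlation ended each camera call. Depth limits genes near 1 FPKM, where 42.9 to 62.8 fragments stand behind the median gene.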

Other observations

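The tests on the prolactin family were chosen after the result was seen, and that on transcript length replaced a rank correlation between length and the difference, which came out at 0.154 over 11644 protein-coding genes.

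In the pTGC libraries each of the 11 prolactin family genes was higher in number 3 than in number 2 in both arms, while 0 of 11 differed between the 3 numbers past the threshold (limma adjusted p 0.0661 to 0.122). Between the libraries numbered 3 and 2, averaged over the arms, their median difference was 2.34 on the log2 scale with 11 of 11 positive, against −0.02 for all tested genes. Reads that shift between near-identical members were argued against, since the family sum itself differed by 3.84 times in the arm with the smaller ratio. A trend on transcript length was argued against as well, since subtracting it left 1.02 of the median. The 14 tested giant cell markers outside the family had a median difference of 0.0626 (quartiles −0.03 and 0.29), so they did not move by as much. From TSC to pTGC under saline such markers changed by unlike amounts, such as Hand1 from 193 to 506 FPKM and Serpinb9e from 0.221 to 270. How far they would move with the extent of giant cell differentiation is therefore not known, and that explanation stays open. The difference was not limited to the family. Outside it the lists with the largest medians were replication-dependent histones (0.69, 5 of 6 higher in number 3 in both arms), whose transcripts mostly lack a poly(A) tail, steroidogenic genes (0.60, 7 of 10) and endothelial and blood cell markers (0.41, 5 of 6), and of 23 matrix genes 16 were higher in both arms (median 0.23). Others were lower in number 3, with medians of −0.23 for labyrinth markers (8 of 13 lower in both arms), −0.23 for retinoic acid targets (10 of 16) and −0.19 for NF-kB genes (7 of 11). Of all 14681 tested genes outside the family 3548 (24.2%) were higher in number 3 in both arms and 4867 were lower in both. No list was tested in this comparison. Tpbpa, too low for the tests and picked after its values were seen, was also highest in the libraries numbered 3 (3.31 and 2.41 FPKM). The tested spongiotrophoblast and glycogen cell markers had a median of −0.03. A difference in the cells and a difference in the preparation of the libraries both stay open. No biological explanation was tested further, since the design gives no group for the replicate number. With the arm in the model 21 genes differed between numbers in pTGC and 2 in TSC, 0 of them prolactin genes.

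The replicate numbers went together across arms in pTGC. The deviations of 2 libraries with the same number from their group means correlated across genes at 0.537, 0.275 and 0.443 for numbers 1, 2 and 3 in pTGC, and at 0.0239, −0.103 and −0.385 in TSC. Libraries of different arms and different numbers correlated at −0.411 to 0.0323 in pTGC and at −0.407 to 0.436 in TSC. The TSC arms were therefore not paired by number, but these values do not show that their libraries were independent. Between pTGC and TSC libraries of the same number the correlations ran from −0.196 to 0.370.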
